A study of Homo sapiens with 4 samples.

How the data were processed

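Gene expression was measured in DLD1, an established human colorectal cancer cell line, on 4 one-colour Agilent arrays. Per the labels, lentivirus carried either a control short hairpin RNA (shControl) or a hairpin against the forkhead transcription factor FOXQ1 (shFOXQ1) into the cells. Puromycin was added after 48 hours and selection went on for 20 days, which gave 1 stable line per hairpin. Cy3-labelled cRNA was made from 0.5 ug of total RNA, per the labels' protocols. Each group holds 2 arrays that the labels call biological replicates.

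The scanner values are intensities that the authors deposited as Agilent Feature Extraction output, 1 array per sample. Per the file headers the software version was 11.0.1.1, while the submitters' processing notes name version 9.1. The processed signal in these files is an intensity already corrected for background and not normalized between arrays, per the file headers. A table of the authors' values for 24847 probes was deposited as well. Set against the scanner files, each of its columns followed the log2 of that array's processed signal (r from 0.9997 to 0.9999 across probes), so the authors' values were read as log2 values normalized between arrays. The medians of its columns were 8.00 on each array. Its normalization method is not given in the sources used here and it served only as an alternative.

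Spots of control type and spots marked as non-uniform or population outliers were left out, and the remaining spots of a probe were averaged. This left 34127 probes, of which 49 had no usable spot on at least 1 array. No spot was saturated. The log2 of the processed signal was taken and the 75th percentile of each array over these probes was subtracted. A probe was kept if it was well above background on both arrays of at least 1 group, which held for 24189 probes. A gene was represented by its kept probe with the highest mean over the 4 arrays, giving 19713 genes. Names came from the accession of each probe, matched without version numbers to RefSeq annotation of assembly GRCh38.p14; 25771 probes (75.5%) had a match, and other probes kept the name in the files. The array design refers to hg19, so no coordinates are given. Of 3767 genes with several kept probes, 136 had probes past the threshold in both directions.

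Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom, estimated prior degrees of freedom 1.23), with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values are two-sided. Levels are given as log2 signal relative to the 75th percentile of the array, as mean ± SD over the 2 arrays of a group. For genes well above background in 1 group only, an at-least fold is given. It sets the mean of the bright group against a dim-group mean in which each array counts with the higher of its own value and the lowest signal of any probe well above background there. Such genes had no probe above background in the dim group.

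Before the data were examined, 22 gene lists, the rule for naming genes and the alternatives were fixed. Lists with at least 5 measured members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The naming rule took FOXQ1, then the 12 largest changes in each direction among genes past the threshold, well above background on all 4 arrays, with non-overlapping groups and a gene symbol. It added the 3 largest at-least folds per direction, and up to 4 members of each list with the largest absolute change. Some genes that the rule named are not reported here. Other genes named in the text were chosen after their values were seen.

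The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, the authors' table, no filter or a stricter filter on dim probes, the mean of a gene's probes, a trended and robust variance model, a replicate block, and leaving out each array. The median spot signal stood in for the mean signal in the normexp alternative, because the files hold no mean signal column. Cyclic loess normalization was added after seeing the data.

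On simulated arrays with the means of the 19713 genes, and their spreads shuffled among the genes, 200 genes were changed by known amounts. At a log2 change of 0.5, 24 of 69 changed genes were recovered, at 1 it was 41 of 64 and at 2 it was 48 of 67. There were 7 false calls in all. In the data 9068 genes passed, so the adjustment was stricter on the simulated arrays. These shares therefore do not give the recovery in the data. A list shifted by 0.6 was called and none of the others was, but with an estimated correlation the call count was 0, so that test missed a shift of this size. The simulated genes varied independently of one another and the lists were simulated once. The run therefore does not show how often the preset correlation gives false calls for lists whose genes vary together.

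All 4 arrays lay on 1 slide in 1 scan. The shControl arrays took positions 1 and 2 and the shFOXQ1 arrays positions 3 and 4, so a difference between these pairs of positions and the hairpin cannot be told apart, and no slide block could be fitted. The number of arrays limits the precision.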

Results

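The series compared DLD1 colorectal cancer cells carrying a control hairpin with DLD1 cells in which a hairpin targets FOXQ1, a forkhead transcription factor, using 2 arrays per group. The 75th percentile of the background-corrected signal was 916 and 938 on the shControl arrays and 738 and 697 on the shFOXQ1 arrays. Between 69.3% and 69.8% of probes were well above background on the shControl arrays, against 71.2% and 75.6% on the shFOXQ1 arrays. Arrays of one group correlated across genes at 0.996 for shControl and 0.998 for shFOXQ1, where genes are not independent replicates. For 453 probes printed as 10 spots each, 76 differed between the shControl arrays and 45 between the shFOXQ1 arrays at an unadjusted p under 0.05 (22.6 by chance), so the replicates differed by more than spot noise. Beyond spot noise these probes had an SD of 0.03 within shControl and 0.02 within shFOXQ1 on the log2 scale, against 0.35 between the groups. Each group was 1 stable line, and p-values measure only the spread between these arrays, which may be technical.

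FOXQ1, the targeted gene, was lower on both shFOXQ1 arrays. Its level was 5.20 ± 0.04 (SD, n = 2) in shControl, with 5.17 and 5.23 on the single arrays, and 3.90 ± 0.04 (SD, n = 2) in shFOXQ1, with 3.88 and 3.93. The log2 fold change was -1.30 (SE 0.04, 95% interval -1.43 to -1.17), which left 40.7% of the control signal (limma adjusted p = 0.00516). Without shControl replicate 1 or 2 the value was -1.33 and -1.27, and it passed (adjusted p = 0.0402 and 0.0365). Without shFOXQ1 replicate 1 or 2 it was -1.27 and -1.32, with an adjusted p of 0.0636 and 0.0624, the lowest of any gene there, and no gene passed.

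Between the lines, GPA33, a cell-surface antigen of intestinal epithelium, rose most among the genes with a symbol that were detected on every array. Its log2 fold change was 2.75 (SE 0.04), from -2.46 ± 0.05 to 0.29 ± 0.04 (SD, n = 2 each). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 2.49 (SE 0.03). DUOX2, an epithelial NADPH oxidase that releases hydrogen peroxide, rose by 2.42 (SE 0.03), and its maturation factor DUOXA2 by 1.90 (SE 0.07). The cytokine IL1B rose by 2.39 (SE 0.09) and the immune checkpoint ligand VTCN1 by 2.10 (SE 0.08). The other genes in the upper 12 were SAMTOR, FAXDC2, ZMIZ1-AS1, ALDOC, KCTD18 and DNMT3L, with log2 fold changes between 1.70 and 1.93. The 2 kept probes of SAMTOR gave 1.93 and 0.56.

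MYBPH, a myosin-binding protein gene, fell most among the genes with a symbol that were detected on every array. Its log2 fold change was -1.84 (SE 0.18). The chemokine genes CCL20 (-1.63, SE 0.03) and CXCL1 (-1.55, SE 0.04) fell, as did the inducible heat-shock chaperone gene HSPA1B (-1.57, SE 0.04), whose probe may share signal with the near-identical HSPA1A. S100A8 (-1.54, SE 0.13) and S100A9 (-1.46, SE 0.04), which encode the subunits of calprotectin, fell together. The other genes in the lower 12 were ESS2, EIF5A, KRTAP3-1, SERPIND1, PRR9 and CRTAM, with log2 fold changes from -1.54 to -1.50. Adjusted p in these 24 genes lay between 0.00516 and 0.00833. An alternative with normexp background correction and quantile normalization, called the normexp setting here, adds 50 to every signal before the log and so compresses dim genes. There 15 of the 24 shrank by over 1.5 times, and all kept their calls. GPA33, at 2.15, then rose less than ANGPTL4, at 2.26. Among them DUOX2 was at 1.46, SAMTOR at 1.04, DUOXA2 at 0.90, VTCN1 at 0.69 and IL1B at 0.62, and ALDOC, FAXDC2, ZMIZ1-AS1 and DNMT3L were at 1.14, 0.83, 0.55 and 0.49. MYBPH was at -0.62 and no longer fell most, S100A8 and S100A9 were at -0.56 and -0.47, and ESS2, PRR9 and SERPIND1 at -0.87, -0.71 and -0.50.

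**Figure D1:**
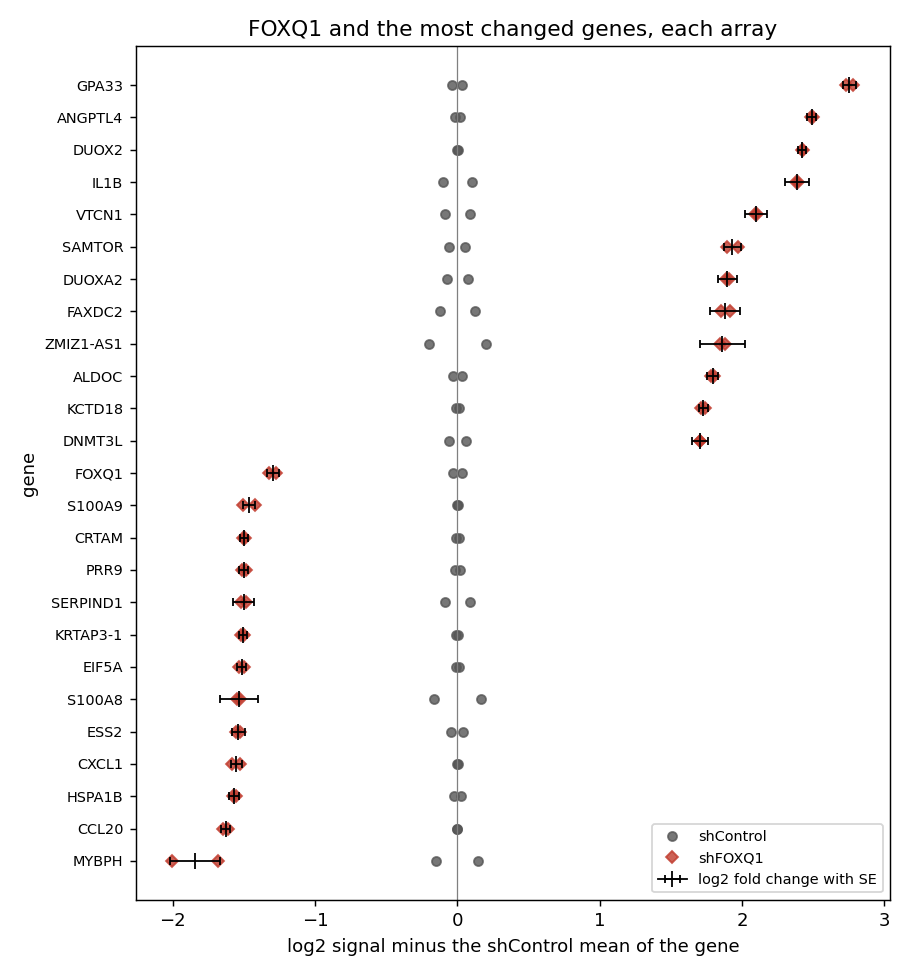
Log2 signal of each array minus the gene's shControl mean, for FOXQ1 and the 24 most changed genes; grey circles are the shControl arrays, red diamonds the shFOXQ1 arrays, and black bars the log2 fold change with its SE. The FOXQ1 fold change is -1.30, and the extremes are GPA33 at 2.75 and MYBPH at -1.84.

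Over all 19713 genes, 9068 passed an adjusted p of 0.05 (46.0%), of which 4871 were higher (53.7%) and 4197 lower in shFOXQ1. With median scaling the balance turned, at 3056 higher (44.6%) and 3800 lower. The balance also went with brightness. In brightness decile 1, the dimmest, 295 genes were higher and 87 lower, with a median log2 change of 0.23 over its genes. In decile 10, the brightest, 386 were higher and 617 lower, with a median of -0.04. This trend was removed only in the tests of the hypoxia and histone lists. It is not free of the filter, which kept genes well above background in 1 line only. Among genes with a symbol these were 297 in shFOXQ1 and 26 in shControl. The median log2 change of all genes was 0.04, against -9.9e-05 with no filter on dim probes and 0.02 with the stricter filter. The deciles were not computed under those filters. Most changes were small, with a median absolute log2 change of 0.38 among the 9068 changed genes, and 425 reached an absolute log2 fold change of 1 (271 higher, 154 lower). The groups did not overlap for 76.2% of genes, where chance gives 33.3%. Without either shFOXQ1 array the limma count was 0, with 8434 and 8266 genes at an unadjusted p under 0.05, and it was 5058 and 5737 without shControl replicate 1 and 2.

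Genes of the hypoxia and glycolysis list rose together. Of 20 measured members 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.64. ALDOC, a glycolytic aldolase, rose by 1.79 (SE 0.04), NDRG1 by 1.55 (SE 0.07), the oxygen-sensing prolyl hydroxylase EGLN3 by 1.53 (SE 0.03) and PDK1, a kinase that inhibits pyruvate dehydrogenase, by 1.34 (SE 0.03). The camera adjusted p of limma was 8.44e-07, and the adjusted p was 0.451 with an estimated correlation. Among angiogenic factors 10 of 19 rose and 5 fell (11 and 6 adjusted over the list alone), with ANGPTL4 at 2.49 against CXCL1, CXCL8 and CXCL2 at -1.55, -1.45 and -1.06, and the list did not pass (adjusted p = 0.476).

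Inflammatory genes downstream of NF-kappaB fell on balance, with 12 of 21 lower and 4 higher (14 and 4 adjusted over the list alone) and a median log2 fold change of -0.31. CCL20, CXCL1 and CXCL8 (-1.45, SE 0.05) fell while IL1B rose, so the list's members moved in both directions. In the normexp setting CXCL8 was at -0.90 and IL1B at 0.62. CXCL1, CXCL2 and CXCL3 are similar in sequence and their probes may share signal; both kept CXCL1 probes fell, at -1.55 and -1.22. The list's camera adjusted p was 0.00955, and the adjusted p was 0.451 with an estimated correlation.

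Cell cycle and DNA replication genes fell on balance, with 16 of 30 lower and 7 higher, the same counts adjusted over the list alone, and a median of -0.15. CDC6, which licenses replication origins, fell by 0.87 (SE 0.06), the transcription factor E2F1 by 0.84 (SE 0.03) and the ribonucleotide reductase subunit RRM2 by 0.74 (SE 0.03), whereas the mitotic kinesin KIF11 rose by 0.67 (SE 0.04). The camera adjusted p was 0.0356, and the adjusted p was 0.451 with an estimated correlation. The list passed in 8 of 16 alternatives, some of which leave the camera test as it was. In the Wnt/beta-catenin list 10 of 25 members fell and 6 rose, again also adjusted over the list alone. The stem cell receptor LGR5 (-0.89, SE 0.03) and the pathway antagonists NKD1 (-0.88, SE 0.03) and APCDD1 (-0.84, SE 0.04) fell. MMP7 was at 1.13 (SE 0.47, adjusted p = 0.144), and the list did not pass (adjusted p = 0.233). The normexp setting gave -0.43 for CDC6, -0.55 for NKD1 and 0.25 for MMP7. MMP7 was at 0.53 without shFOXQ1 replicate 1 and at 1.73 without replicate 2, so its value depends on single arrays.

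Ribosomal protein genes rose by small amounts: 15 of 26 were higher and 0 lower, also adjusted over the list alone, with a median of 0.20 and a camera adjusted p of 0.00178 (adjusted p = 0.451 with an estimated correlation). RPLP1 was at 0.36 (SE 0.07) and RPL27 at 0.30 (SE 0.03), both past the threshold. With quantile normalization the list's median was 0.03 and its adjusted p 0.604, so this call depends on the normalization. RPLP1 and RPL27 were then at 0.16 and 0.11 and did not pass (adjusted p = 0.236 and 0.115). Of 17 housekeeping reference genes 7 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.476), with PGK1 at 0.35, TBP at -0.29 and RPLP0 at 0.29. Quantile normalization gave 0.17 for PGK1 and 0.07 for RPLP0, neither past the threshold. Without shControl replicate 1 or 2, RPLP1 (0.43 and 0.29) and RPLP0 (0.26 and 0.32) lost their calls, as did RPL27 (adjusted p = 0.0538 and 0.0529), and TBP did so without replicate 1 (adjusted p = 0.0537).

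**Figure D2:**
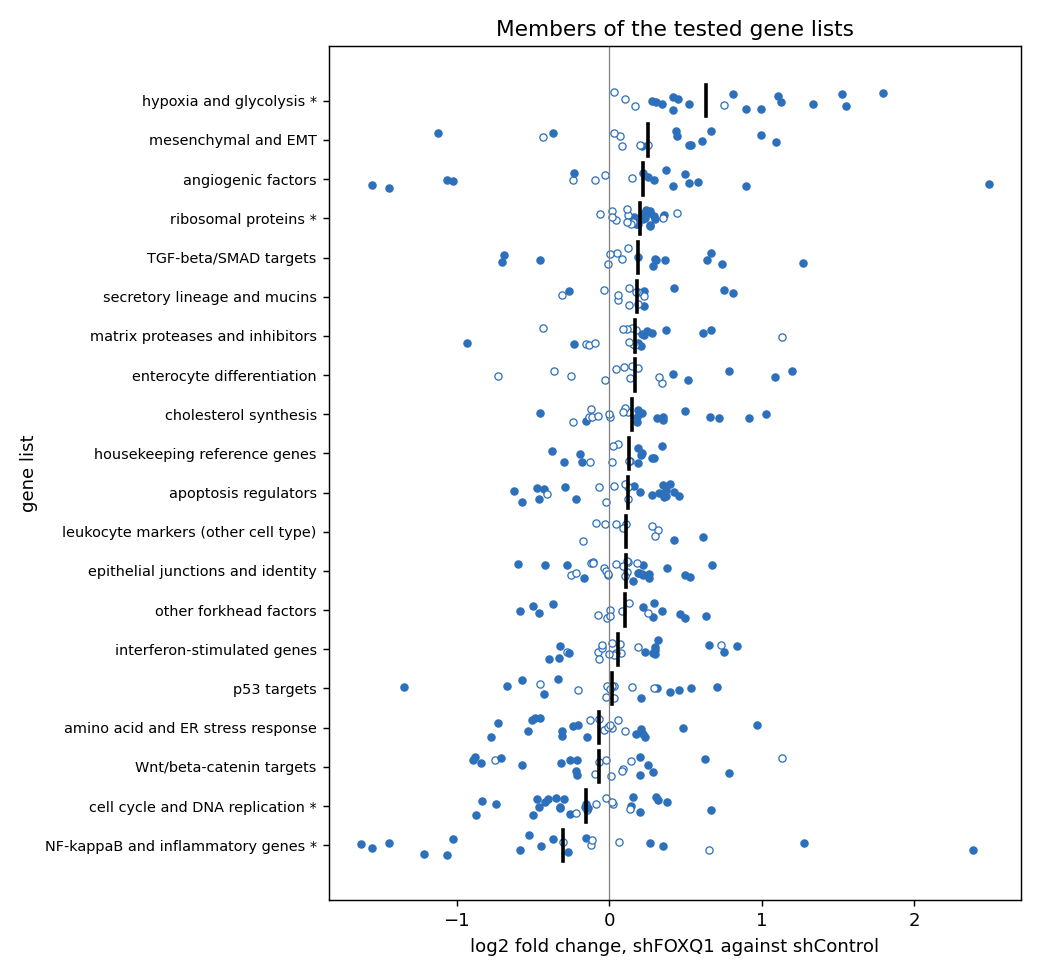
Log2 fold change of every measured member of the 20 tested gene lists; filled circles passed an adjusted p of 0.05 over all genes, open circles did not, black bars are list medians and asterisks mark lists with a camera adjusted p under 0.05. The hypoxia and glycolysis list has the highest median, 0.64, and the NF-kappaB list the lowest, -0.31.

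Lists on cell identity did not pass the camera test. Among epithelial junction genes 11 of 32 rose and 4 fell (15 and 5 adjusted over the list alone; adjusted p = 0.30), including the splicing regulator ESRP1 at 0.68, MARVELD3 at -0.60, DSG2 at 0.53 and CLDN3 at 0.50. Among mesenchymal genes 9 of 17 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0603). The intermediate filament gene VIM rose by 1.09 (SE 0.11) and the collagen cross-linking enzyme LOX by 1.00 (SE 0.05), and the actin-binding TAGLN fell by 1.12 (SE 0.12). Of 16 enterocyte genes 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.165), led by the adhesion molecules CEACAM1 (1.20, SE 0.06), CEACAM5 (1.09, SE 0.14) and CEACAM6 (0.79, SE 0.12). The second CEACAM1 probe gave 0.40. The normexp setting gave 0.49 for VIM, 0.19 for LOX, -0.74 for TAGLN, and 0.63, 0.23 and 0.16 for CEACAM1, CEACAM5 and CEACAM6. CEACAM6 did not pass with quantile normalization (adjusted p = 0.0588), nor CEACAM5 without shControl replicate 1 (adjusted p = 0.0563) or 2 (adjusted p = 0.0612), nor TAGLN without shControl replicate 1 (adjusted p = 0.0514). CDHR5 was at -0.73 (SE 0.83, adjusted p = 0.521), and at 0.12 without shControl replicate 1 and -1.58 without shControl replicate 2; without shFOXQ1 replicate 1 and 2 it was at -0.11 and -1.35. Of 16 secretory genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.129), with TFF3 at 0.81, KLF4 at 0.75, AGR2 at 0.42 and SPDEF, not past the threshold, at -0.31; with median scaling it was at -0.36 and passed (adjusted p = 0.0443), in the normexp setting it passed at -0.16 (adjusted p = 0.0210), and without shControl replicate 1 it was at -0.19 (adjusted p = 0.139). Over the 14 alternatives SPDEF passed in 6 and FOXQ1 in 12.

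The TGF-beta, matrix protease and forkhead lists did not pass either. TGF-beta targets had 9 of 17 higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 0.133), with BHLHE40 at 1.27, SKIL at 0.74, PMEPA1 at -0.70 and SKI at -0.69. The second PMEPA1 probe gave 0.39, and the mean of its probes -0.16 (adjusted p = 0.639). Of 23 matrix proteases and inhibitors 9 rose and 2 fell (12 and 3 adjusted over the list alone; adjusted p = 0.129), and the collagenase MMP1 fell by 0.94 (SE 0.07) while MMP11 rose by 0.61 (SE 0.07). Other forkhead factors had 7 of 18 higher and 4 lower (8 and 4 adjusted over the list alone; adjusted p = 0.476), with FOXL1 at 0.64, FOXF1 at -0.50 and FOXO3 at 0.49. The brightest FOXP1 probe gave -0.59 and its other 2 kept probes 0.64 and 0.69, so FOXP1 has no settled direction. In the normexp setting MMP1 was at -0.18, MMP11 at 0.35, SKIL at 0.26 and FOXF1 at -0.18. Without shControl replicate 1 or 2, SKIL (adjusted p = 0.0722 and 0.0792; 0.0621 with the replicate number as a block) and PMEPA1 (adjusted p = 0.0655 and 0.0646) lost their calls, as did MMP11 without replicate 1 (adjusted p = 0.0519).

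In the metabolic and stress lists single members changed, and no list passed. Cholesterol synthesis genes had 12 of 24 higher and 2 lower (12 and 3 adjusted over the list alone; adjusted p = 0.129), with the sterol sensor partner INSIG1 at 1.03, HMGCS1 at 0.91 and IDI1 at 0.72. In the amino acid and ER stress list 11 of 25 fell and 6 rose (12 and 6 adjusted over the list alone; adjusted p = 0.165), with DDIT4 at 0.97 and SESN2, SLC7A5 and CHAC1 at -0.78, -0.73 and -0.54. Of 21 p53 targets 6 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.861). The p53 list's median was 0.02, while its mean of -0.04 and its camera direction were negative. AEN fell by 1.35 (SE 0.03) and TP53I3 was at -0.67. ZMAT3 was not well above background in shControl and was at least 1.18-fold higher in shFOXQ1 (adjusted p = 0.00687). Its call was lost in the normexp setting, at 0.05 (adjusted p = 0.296), and held in 8 of 13 alternatives. The call of FOXQ1 held in 12 of 14. Apoptosis regulators had 11 of 25 higher and 7 lower (12 and 7 adjusted over the list alone; adjusted p = 0.532), with CASP8, BAX, BAK1 and BIK at -0.63, -0.57, -0.47 and -0.46. Interferon-stimulated genes had 9 of 26 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.397), with IFIT1, IFITM1 and IFIT2 at 0.84, 0.75 and 0.66, the last at 0.42 in the normexp setting. BST2 was not well above background in shControl and did not pass the threshold (adjusted p = 0.104; 0.0464 with the replicate number as a block).

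Some markers of other cell types were measured. Of 11 leukocyte markers 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.360), namely CSF1R at 0.61 and CD68 at 0.42, while CD3E was at 0.32 and did not pass. CD3E depended on single arrays, at 0.55 and 0.10 without shControl replicate 1 and 2 and at 0.19 without shFOXQ1 replicate 2. The normexp setting gave 0.38 for CSF1R and 0.23 for CD68, and CD68 did not pass with median scaling (adjusted p = 0.0527) or with the replicate number as a block (adjusted p = 0.0597). Fibroblast and endothelial lists had 2 and 4 measured members and were too short for the test. PDGFRB rose by 1.38 (SE 0.05). COL1A1 was at -0.63 (SE 0.12) and passed, but its call held in only 5 of 14 alternatives, against 12 for FOXQ1. It was at -0.09 in the normexp setting (adjusted p = 0.127). VWF rose by 0.50 (SE 0.06), a call lost without shControl replicate 1 (adjusted p = 0.0551) or 2 (adjusted p = 0.0568), and ERG, CDH5 and ENG were at 0.18, 0.11 and 0.03 without passing. ERG was at 0.026 without shControl replicate 1 and at 0.33 without replicate 2, where it passed (adjusted p = 0.0453). CDH5 was at 0.05 with median scaling, and ENG lay between -0.13 and 0.20 with 1 array left out. Adjusted over the list alone these counts did not change.

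Among the 15150 tested genes with a gene symbol, some were well above background in 1 line only. These were 297 in shFOXQ1 and 26 in shControl, of which 126 and 18 passed the threshold. Over all 19713 tested genes 46.0% passed. The genes seen in 1 line only were picked by their difference on the same arrays, so their p-values do not test that difference independently. DNMBP-AS1 was at least 4.11-fold higher in shFOXQ1 (adjusted p = 0.0336), SFTPB at least 2.75-fold (adjusted p = 0.0137) and SGK2 at least 2.73-fold (adjusted p = 0.00961). In the other direction TCF24 was at least 4.64-fold higher in shControl (adjusted p = 0.00516), SPOCD1 at least 4.42-fold (adjusted p = 0.0122) and MORN5 at least 3.65-fold (adjusted p = 0.0145). These bounds hold only for the background correction behind them: in the normexp setting the log2 fold changes, all past the threshold, were 0.42, 0.30 and 0.25 for DNMBP-AS1, SFTPB and SGK2 and -0.57, -0.36 and -0.38 for TCF24, SPOCD1 and MORN5, all smaller than the bounds. DNMBP-AS1 did not pass with no filter on dim probes (adjusted p = 0.0726), nor SFTPB with the replicate number as a block (adjusted p = 0.0532). Without shControl replicate 1 or 2 the calls of DNMBP-AS1 (adjusted p = 0.0856 and 0.0520), SFTPB (0.0637 and 0.0543) and MORN5 (0.0670 and 0.0593) were lost. The larger share of probes above background on the shFOXQ1 arrays goes with the uneven counts.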

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

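Cyclic loess normalization was chosen after seeing the data; the other settings were fixed before. The main counts were 9068 changed genes, 4871 higher and 4197 lower. With no filter on dim probes they were 5784, 3059 and 2725; with the replicate number as a block 5249, 2824 and 2425; at an adjusted p under 0.01 3771, 1951 and 1820; with an absolute log2 fold change of at least 1 as well 425, 271 and 154. Median scaling gave 6856, 3056 and 3800, so the share higher fell from 53.7% to 44.6%. Leaving out 1 array gave 0 to 5737 changed, 0 to 3006 higher and 0 to 2731 lower genes, and FOXQ1 between -1.33 and -1.27. The counts of 0 came without shFOXQ1 replicate 1 or 2, where the spread comes from the shControl pair alone and the lowest adjusted p of any gene was 0.0636 and 0.0624. Without either shControl array the same 1 residual degree of freedom is left, a lone array is again assumed to vary like the other group, and 5058 and 5737 genes passed, so these conditions do not account for the counts of 0, whose cause was not tested. Without shControl replicate 1 and 2, 14 and 11 of the 96 named genes past the threshold lost their calls. With normexp (offset 50) and quantile normalization 54 of 107 named genes shrank by over 1.5 times, 5 calls were lost, and the median level of the 54 was -3.98 against 1.12 for the others. The replicate numbers showed no pairing: the deviations of same-numbered arrays correlated at -0.09 across genes. A slide block was not run, as there is 1 slide.

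Of the 4 shifted lists, 2 passed with quantile normalization and with the authors' values. These settings gave nearly the same values, with 8564 and 8607 changed genes and median log2 changes of 0.03325 and 0.03321 over all genes. They are therefore not separate checks. With an estimated correlation 0 lists passed. On simulated arrays the test with an estimated correlation also missed a list shifted by 0.6. A list that fails it is therefore not shown to be unshifted. The cause of the other losses was not settled. Leaving out 1 array gave 3 to 4 lists. The hypoxia and NF-kappaB lists passed in 15 of 16 alternatives each, ribosomal proteins in 12 and cell cycle in 8. These counts include the trended and robust variance model and a minimum of 10 measured members. Neither alters the camera test here, so they repeat the main calls. Cholesterol synthesis passed with normexp and quantile normalization only (adjusted p = 0.0192, range over alternatives 0.0192 to 0.451).

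Of the directions that turned, only that of FOXP1 had passed the threshold. ENG was at -0.017 with median scaling, -0.075 with cyclic loess and -0.13 to 0.20 with 1 array left out, and CDHR5 at -1.58 to 0.12 with 1 array left out. FOXP1 was at 0.25 with the mean of its probes, which disagree. The camera direction of the p53 list turned with no filter (median 0.021), the mean of probes (0.028) and cyclic loess (0.055), and the housekeeping list with normexp and quantile normalization (0.020) and the mean of probes (0.011). Signal over background limits the genes seen in 1 line only.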

Other observations

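The lists in this part were put together after the changed genes had been seen, and so were the tests below, except the slide-position tests and the growth-factor withdrawal test, whose list members had not been looked at, apart from 2 of 20 that the p53 list also holds. How the spread of the slide-position steps was judged, and the criteria of the ribosomal scaling and S-phase tests, were settled after their results were seen. Ribosome biogenesis factors, which assemble ribosomal subunits in the nucleolus, fell as a group: 41 of 50 were lower and 1 higher in shFOXQ1, with a median log2 fold change of -0.54. MRTO4 (-1.09, SE 0.05), RRS1 (-1.08, SE 0.03) and the nucleolar methyltransferase NOP2 (-0.93, SE 0.03) were among them. Heat shock response genes fell as well, 14 of 21 lower and 1 higher with a median of -0.51, including the co-chaperone DNAJB1 (-0.96, SE 0.04) and the chaperone HSPA8 (-0.90, SE 0.05). Of 59 replication-dependent histone genes 39 were lower and 0 higher, with a median of -0.35; many are near-identical in sequence, so their probes are not independent. Adjusted over the 6 lists tested in this way, the camera adjusted p of these 3 was 2.27e-13, 2.12e-05 and 2.46e-11. With an estimated correlation the adjusted p was 0.0690, 0.0807 and 0.0807. Because these 3 lists were chosen after the changes were seen, the p-values describe the lists and do not test them. The medians stayed negative under each scaling.

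For the rise of the hypoxia list, a brightness trend between arrays is argued against, since the list's median was 0.61 after the change of equally bright genes was removed. A steady gradient along the slide is argued against too: it would move the list by 0.32 per position, and the steps were -0.03 within shControl and -0.00052 within shFOXQ1. A denser or more depleted culture of the shFOXQ1 line may have raised these genes. In support, a growth-factor withdrawal list (FOXO-type) had a median of 0.40, with 15 of 20 members higher and 0 lower (10 higher with median scaling). Its camera adjusted p was 5.85e-05. With an estimated correlation the adjusted p was 0.166, from a test that missed a simulated list shift of 0.6. This support is weak, because the list cannot tell a depleted culture from an effect of the hairpin on the same genes. The loss of FOXQ1 itself stays open, because each hairpin is 1 line, and so does a difference between the pairs of slide positions.

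The rise of ribosomal protein genes cannot be told apart from the scaling of the brightest probes. Its median was 0.032 with quantile normalization, which fixes the brightest values by construction, and 0.26 with cyclic loess; all 26 genes lie among the brightest 5% of genes, whose other members had a median of 0.01. A steady gradient along the slide is argued against as the whole cause. It would move the list by 0.10 per position, and the steps were 0.039 within shFOXQ1 and -0.02 within shControl. The 95% bootstrap intervals, drawn over the list's genes, were 0.01 to 0.06 and -0.05 to -0.00054. Each step sets a single array against another, so these intervals hold the spread between genes and not that between arrays.

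The fall of histone genes was not removed with the brightness trend, after which their median was -0.40. Fewer cells in S phase stay open: the median of 13 S-phase and replication genes was -0.32 (-0.18 with normexp and quantile normalization), but all 13 belong to the cell cycle list and had been seen to fall on balance, so this value does not test the explanation. A change in the polyadenylation of histone transcripts was not tested.

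The number of changed genes was set against the other splits of the 4 arrays into pairs. Of 3 splits only 1, the real one, gave as many genes (9068, against 0 for both others with limma, which had 121 and 282 genes at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05. Each other split pairs arrays of different lines, so the difference between the lines adds to the spread within its pairs. Its low count is therefore no measure of what chance gives.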
